A study of Rattus norvegicus with 10 samples.

How the data were processed

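Strand-specific mRNA libraries were made from total RNA of the left hippocampus with the KAPA mRNA-Seq Hyper Prep kit and sequenced as single-end reads of 50 bases on a HiSeq3000, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.19.1.403, STAR 2.7.9a, Partek and DESeq2 and the rat build rn6, without saying which step each served. The program that counted reads, its strand setting and the gene annotation are not given in the sources used here, so that reads of a gene and of an overlapping or antisense neighbour may not have been told apart.

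The authors deposited 2 tables with 1 column per library. The first holds estimated counts per gene model, with 83.2% of the deposited values whole. The second holds the authors' CPM, which equal the deposited estimated count scaled by the column total, plus an offset of 1e-04. The count table has 14834 lines for 13686 gene symbols, and 799 symbols have more than 1 line (1947 lines in all), from gene models or genomic copies that share a symbol. Estimated counts were summed per symbol and then rounded to whole numbers. Values of genes with near-identical copies, such as ribosomal protein genes, are uncertain where the counting split reads between copies. Coordinates are given as listed in the deposited table, and whether its start positions count from 0 or from 1 was not settled. Mitochondrially encoded genes were not analysed here. No 2 libraries of a group held the same values within sampling noise, since the chi-square statistic per degree of freedom between replicates ran from 4.52 to 32.4.

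Untreated and BT-11 libraries were compared in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust dispersion, TMM normalization and the default filter on low counts by group, which kept 11771 genes and left out 1915. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested. The biological coefficient of variation was 0.14. The 95% intervals of fold changes come from the same fit. Of 49 gene lists for cell types, neighbouring brain regions and pathways, 46 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The 3 lists not tested were T and NK cell markers, mitochondrially encoded genes and sex-linked genes. For 18 lists of cell or region markers, a score per animal was the mean over the list of log2 CPM (prior count 2) centred per gene, compared by an exact permutation test over all 252 assignments. P-values of lists count genes that vary together, and tests on libraries measure the spread between these animals.

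Genes named in the text were chosen by a rule: those past an adjusted p of 0.05 with the largest changes (there were 0); where fewer than 10 pass, the 10 with the smallest p in each direction with a mean of at least 1 CPM and a gene name in place of a placeholder; a fixed set of drug target, disease and glial genes, of which 1 is not reported here; up to 4 members with the smallest p of each list past camera's test; and up to 3 members of each list past 0.05 adjusted over the list alone. The test, the gene lists, this rule and the alternative settings described last were fixed before the data were examined. The alternatives added after the data were seen are the untouched lines of the table, the removal of ribosomal RNA genes, the omission of 2 pairs of untreated libraries, the removal of a trend with transcript length, a joint covariate of 3 marker scores, and a covariate that separates replicate numbers 4 and 5 from 1 to 3. The fits within those 2 sets of replicate numbers were also chosen after the data were seen.

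The settings fixed beforehand were DESeq2 1.42.0, limma-voom with and without sample weights, other normalizations and filters, a non-robust fit, 1 surrogate variable (sva 3.50.0), marker scores as covariates, the authors' CPM on a log2 scale with a pseudocount of 1 or 0.1, a block for the replicate number, and the omission of each library in turn. The edgeR step was tested on simulated counts for 11771 genes with 200 changed genes per run in 5 runs, where 4.63% of the called genes were unchanged ones. With no changed genes, a mean of 552 genes had an unadjusted p under 0.05. Genes were drawn independently in these runs, without variation that they share between libraries. Reads carry no molecular identifiers, so intervals cover the spread the fit estimates and counting error, not amplification.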

Results

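RNA of the left hippocampus was sequenced from 10 male TgF344-AD rats, a transgenic line used as a model of Alzheimer disease. Of these, 5 rats ate plain chow (untreated) and 5 received the compound BT-11 from 5 months of age for 6 months. All were sampled at 11 months, and each library came from a separate animal. Ketamine and xylazine are listed for all of these animals, at the same doses in both groups. BT-11 is known as an orally active ligand of the lanthionine synthetase C-like protein LANCL2. The design asks which hippocampal genes differ between treated and untreated transgenic males. The summed count per library was 9578410 ± 972638 in untreated rats and 10538200 ± 618560 in BT-11 rats (SD, n = 5 each). The lowest total was 8984439 and the highest was 11301545. All fold changes below are BT-11 relative to untreated, on the log2 scale, with the standard error of the fit.

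Among single genes, the largest evidence for a higher level with BT-11 was at B4galt3, Dclk3, Map3k3 and Brpf1, and for a lower level at Otof, Ctnnbip1, Agt and Tubb2b, but none of the 11771 genes tested passed an adjusted p of 0.05. B4galt3, a galactosyltransferase of the Golgi (build rn6, chromosome 13, 89643880 to 89649869 as listed, plus strand), was at 37.2 ± 2.27 CPM in untreated and 47.6 ± 2.18 CPM in BT-11 hippocampi (SD, n = 5 each). Dclk3, a kinase of the doublecortin-like family (chromosome 8, 119691567 to 119744485, plus strand), was at 9.35 ± 1.55 and 14.9 ± 1.61 CPM. Every BT-11 library lay above every untreated library for both genes, and also for Map3k3, Brpf1 and Htr1b. Htr1b, which encodes a serotonin receptor, had a log2 fold change of 1.248 ± 0.273 (SE), and Wfs1, a protein of the endoplasmic reticulum used here as a marker of CA1 pyramidal neurons, 1.253 ± 0.301. Untreated replicate 3 held 284 CPM of Wfs1, against 91.9 to 130.3 CPM in the other untreated libraries. Cttnbp2, Dipk2a, Mmp19 and Zfhx4 had log2 fold changes of 0.41, 0.59, 0.97 and 0.71.

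Otof, the gene of the calcium sensor otoferlin (chromosome 6, 27328406 to 27424864, plus strand), was at 28.7 ± 7.81 CPM in untreated and 14.4 ± 1.77 CPM in BT-11 libraries, a log2 fold change of -1.01 ± 0.179. Agt, which encodes angiotensinogen and is made in the brain mainly by astrocytes (chromosome 19, 57321639 to 57333434, minus strand), was at 186 ± 20.8 and 141 ± 9.58 CPM, with a log2 fold change of -0.41 ± 0.0842. Ctnnbip1, an inhibitor of beta-catenin, and Tubb2b, a beta-tubulin, had values of -0.45 ± 0.0903 and -0.41 ± 0.0866. For Ctnnbip1, Agt, Tubb2b, Rnd1, Bves, Acss2 and Nppc, every BT-11 library lay below every untreated library. Bves, Fibin and Shroom3 had log2 fold changes of -1.07, -1.06 and -0.96, at mean untreated levels of 3.48, 7.67 and 11.2 CPM. All of these 20 genes had an adjusted p of 0.402 in edgeR's quasi-likelihood test, with unadjusted p from 9.87e-05 for Otof to 0.00125 for Wfs1.

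**Figure D1:**
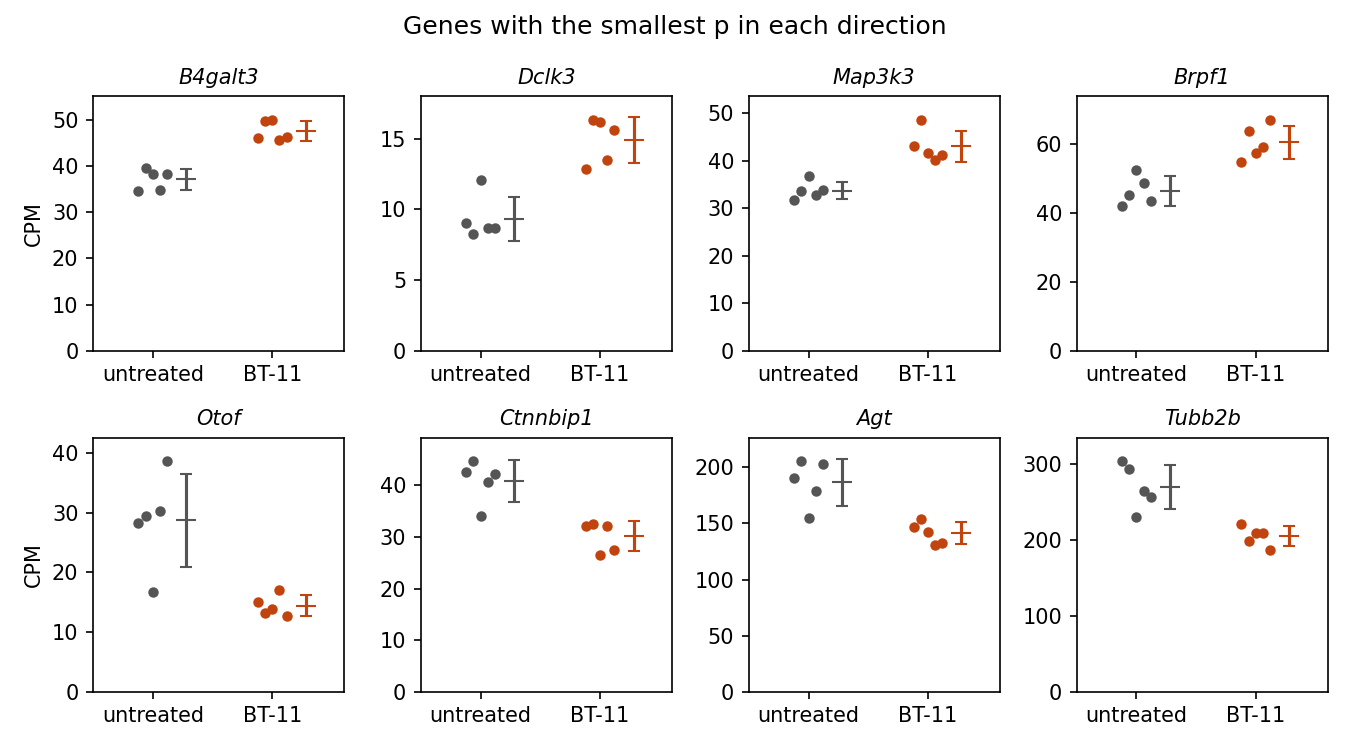
CPM (vertical axis, from 0) of 8 genes in each library, untreated in grey and BT-11 in orange, with the group mean and SD (n = 5) beside the points. The upper panels hold the 4 genes with the smallest p among those higher with BT-11 and the lower panels the 4 among those lower; B4galt3 went from 37.2 to 47.6 CPM and Otof from 28.7 to 14.4 CPM between the group means, and no gene passed the adjusted test.

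Across all genes, edgeR called 0 at an adjusted p of 0.05, with a smallest adjusted p of 0.402, while 1070 genes had an unadjusted p under 0.05, 476 of them higher and 594 lower with BT-11. DESeq2 called 40 genes, 13 higher and 27 lower, among them Otof, Ttr, B4galt3, Dclk3 and Agt. Leaving out untreated replicate 3 gave 62 genes in edgeR, 31 in each direction, among them Otof, Dclk3, Wfs1, Zfhx4 and Shroom3. That library was the highest untreated one in Wfs1 (284 CPM) and Dclk3 (12.1 CPM), so its omission favours the calls of these genes. The count of 62 was not set against other splits of the libraries. Fold changes followed transcript length (Spearman correlation 0.166 across genes), with a median of -0.04 in the shortest and 0.03 in the longest of 4 equal groups of genes. The groups did not overlap for 148 genes (1.26% of those tested, where chance gives 0.794%). In simulated data of the same size, the edgeR test called 62% of genes changed 1.5-fold and 85.2% of those changed 2-fold, but 11.6% of those with the smallest simulated change. Each gene was simulated on its own, without the variation that genes of these libraries share. The shares called may therefore overstate what could be detected here. The replicate numbers 4 and 5 separated from 1 to 3 in expression in both groups, a split taken from the data and not given as a batch in the labels. Within numbers 1 to 3 (3 against 3 rats) edgeR called 0 genes, with 893 at an unadjusted p under 0.05. Within numbers 4 and 5 (2 against 2 rats) it called 479 genes, 239 higher and 240 lower. Numbers 4 and 5 were the closest pair of libraries within each group (chi-square per degree of freedom 7.14 and 4.52), which favours calls. With that split as a covariate over all 10 libraries edgeR called 0 genes, with 1312 at an unadjusted p under 0.05.

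The genes closest to the disease model and to the drug showed no difference past the test. Lancl2, the reported target of BT-11, was at 57.9 ± 4.23 CPM in untreated and 57.8 ± 4.42 CPM in BT-11 hippocampi (SD, n = 5 each), with a 95% interval of its log2 fold change from -0.18 to 0.15. The interval for rat App, the amyloid precursor protein gene, ran from -0.15 to 0.22. Those for Mapt, which encodes tau, and Prnp, the prion protein gene, ran from -0.15 to 0.11 and from -0.21 to 0.10. Apoe, a lipid carrier made by astrocytes and microglia, had a log2 fold change of -0.21 ± 0.106 (SE), with an adjusted p of 0.594 in edgeR. The microglial receptor gene Trem2 had -0.21 ± 0.144, the microglial marker Aif1 -0.11 ± 0.133 and the MHC class II chaperone gene Cd74 -0.15 ± 0.222. Gfap, the astrocyte filament gene, was at 1833 ± 353 and 1955 ± 176 CPM. Tnf and Il1b had at most 4 counts in any library and Pparg at most 8, so that a difference in these genes was not detectable at this depth. Il10 was not analysed here. Among 35 tested Alzheimer disease and amyloid genes, 18 were higher and 17 lower, with none past the test over all genes or adjusted over the list alone.

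Over all 10 libraries, neuronal and astrocytic marker genes were mostly lower with BT-11. Of 16 pan-neuronal markers 15 were lower, with a mean log2 fold change of -0.22, and the list passed camera's test against the other genes with a preset correlation (adjusted p = 1.42e-05) but not otherwise (adjusted p = 0.719 with an estimated correlation). Nefm, a neurofilament gene, was at 445 ± 66.2 and 321 ± 33.1 CPM (SD, n = 5 each), while Rbfox3, which encodes the neuronal nuclear antigen NeuN, went the other way, at 125 ± 10.2 and 149 ± 6.87 CPM. Adjusted over the list alone, 5 pan-neuronal markers passed, 4 lower and 1 higher, against 0 over all genes. All 16 astrocyte markers were lower, with a mean of -0.18 (adjusted p = 6.29e-05, and adjusted p = 0.719 with an estimated correlation). Gjb6 and Gja1, both gap junction genes, had log2 fold changes of -0.50 ± 0.139 and -0.21 ± 0.08, and no astrocyte marker passed adjusted over the list alone. Of 33 synaptic vesicle and scaffold genes 22 were lower (adjusted p = 0.0271, and adjusted p = 0.719 with an estimated correlation), with a mean of -0.09, and with Stx1a at -0.50 (65.6 CPM in BT-11 replicate 2 against 98.7 to 111 CPM in the other BT-11 libraries) and Cplx1 at -0.33 but Camk2b at 0.28. By replicate number, the astrocyte mean was -0.01 in numbers 1 to 3 and did not pass there (adjusted p = 0.483 in camera, and adjusted p = 0.797 with an estimated correlation). In numbers 4 and 5 it was -0.34 (adjusted p = 7.54e-12 in camera, and adjusted p = 0.602 with an estimated correlation). Whether a list differs between these sets was not tested. In the same order, the synaptic mean was 0.01 and -0.19, and the pan-neuronal mean -0.24 and -0.14. In 31 alternatives with the preset correlation and no replicate block, the pan-neuronal and astrocyte calls were kept in all 31 and the synaptic call in 24, being lost without untreated replicate 4, untreated replicate 5 or BT-11 replicate 2, among others.

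Over all libraries, genes of energy metabolism and protein turnover had small, mostly lower values. Of 42 nuclear-encoded oxidative phosphorylation genes 40 were lower, with a mean log2 fold change of -0.11 (adjusted p = 2.18e-05, and adjusted p = 0.719 with an estimated correlation). Cox6c had -0.26 ± 0.114 and Atp5f1b -0.13 ± 0.0577 (SE). Of 26 hypoxia and glycolysis genes 20 were lower (adjusted p = 6.29e-05, and adjusted p = 0.662 with an estimated correlation), with the glycolytic enzyme genes Tpi1, Pfkl, Pkm and Gpi at -0.26, -0.33, -0.23 and -0.24. Of 27 oxidative stress and NRF2 genes 23 were lower (adjusted p = 0.00272, and adjusted p = 0.719 with an estimated correlation), with Me1 at -0.34 and Srxn1 at -0.23. Of 31 proteasome genes 28 were lower, by a mean of -0.08 (adjusted p = 0.00423, and adjusted p = 0.719 with an estimated correlation). Of 65 cytosolic ribosomal protein genes 60 were lower, by a mean of -0.08 (adjusted p = 0.0203, and adjusted p = 0.867 with an estimated correlation). No member of these 5 lists passed over all genes or adjusted over the list alone. The ribosomal protein list turned to a mean of 0.05 with 1 surrogate variable in the design and then passed as higher (adjusted p = 0.0234, and adjusted p = 0.893 with an estimated correlation). Without untreated replicates 1 and 2, an alternative chosen after the data were seen, the means turned to 0.01 for oxidative phosphorylation and 0.02 for proteasome genes, which lost their calls, and to 0.09 for ribosomal protein genes, which passed as higher (adjusted p = 3.35e-06, and adjusted p = 0.748 with an estimated correlation; adjusted p up to 0.42 over the alternatives). Within numbers 1 to 3 and within numbers 4 and 5 the proteasome mean was -0.14 and 0.03, the ribosomal protein mean -0.13 and 0.04 and the oxidative phosphorylation mean -0.15 and -0.03, so that the first 2 changed direction. Oxidative phosphorylation kept its direction but did not pass camera's test in numbers 4 and 5 (adjusted p = 0.389). Nor did hypoxia and glycolysis (mean -0.04, adjusted p = 0.0701) or oxidative stress and NRF2 genes (mean -0.05, adjusted p = 0.389) pass there. With the trend with transcript length removed, also chosen after the data were seen, the ribosomal protein mean was -0.02 and did not pass (adjusted p = 0.42). Over the same 31 alternatives the call was kept in 31 for hypoxia and glycolysis, 28 for oxidative phosphorylation, 27 for oxidative stress and NRF2, 26 for proteasome and 22 for ribosomal protein genes. The oxidative stress call was among those lost without untreated replicates 1 and 2 (mean -0.04) and without untreated replicate 1 alone (mean -0.07).

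Over all libraries, myelin, immediate early and dentate granule cell genes were mostly higher with BT-11, but the first 2 of these lists did not keep their direction within both sets of replicate numbers. Of 19 oligodendrocyte and myelin markers 18 were higher, with a mean of 0.14 (adjusted p = 0.00357, and adjusted p = 0.719 with an estimated correlation). Opalin, a myelin protein gene, was at 143 ± 13.8 and 194 ± 47.5 CPM (SD, n = 5 each), and the exception was Enpp2, at 318 ± 276 and 169 ± 37.8 CPM, a gene that the choroid plexus also expresses. Of 30 immediate early genes 19 were higher, with a mean of 0.13 (adjusted p = 0.0122, and adjusted p = 0.719 with an estimated correlation), with the activity-induced transcription factor gene Egr1 at 0.59 ± 0.187, Egr3 at 0.47 ± 0.165 and Ier5 at 0.39 ± 0.104 (SE). Of 9 dentate granule cell markers 6 were higher, with a mean of 0.27 (adjusted p = 0.0203, and adjusted p = 0.719 with an estimated correlation), among them Plk5 at 0.68 ± 0.215 and C1ql2 at 0.49 ± 0.217. No member of these 3 lists passed over all genes or adjusted over the list alone. Within numbers 1 to 3 and within numbers 4 and 5 the mean was -0.12 and 0.56 for myelin markers, 0.25 and -0.10 for immediate early genes and 0.36 and 0.15 for dentate markers. The dentate list did not pass camera's test in numbers 4 and 5 (adjusted p = 0.809). The myelin call was lost without untreated replicate 4, among others, and was kept in 26 of the 31 alternatives, the dentate call in 18. The dentate call was lost without untreated replicate 1 or 5 or BT-11 replicate 1 or 3, among others. The dentate score difference of 0.30 was 0.19 without untreated replicate 1. The immediate early call was kept in 28 and lost without untreated replicate 4, BT-11 replicate 1 or BT-11 replicate 3, each with a mean of 0.06 or 0.07.

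Of 11 CA3 pyramidal neuron markers 8 were lower, with a mean of -0.10 over all libraries, -0.24 in numbers 1 to 3 and 0.10 in numbers 4 and 5 (adjusted p = 0.0203 over all, and adjusted p = 0.719 with an estimated correlation). Cpne7, a copine gene, was at 168 ± 53.5 and 78.6 ± 24.3 CPM (SD, n = 5 each) and was the 1 CA3 marker to pass adjusted over the list alone. Prkcd, which the thalamus also expresses, had 1.74 ± 0.643 (SE). The CA3 call was kept in 23 of the 31 alternatives, with means from -0.37 to -0.05, and was lost without untreated replicate 1 or 4 or without BT-11 replicate 1, 2 or 3. Of 8 CA1 markers 7 were higher (adjusted p = 0.0513, and adjusted p = 0.719 with an estimated correlation), and 2 passed adjusted over the list alone, Wfs1 upward and Dcn downward. Dcn, a proteoglycan of fibroblasts, is also among the meningeal markers. The CA1 list passed as higher in 9 of the 31 alternatives. With the replicate block it passed too (adjusted p = 8.54e-05 in camera, and adjusted p = 0.586 with an estimated correlation).

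Among the lists that passed, choroid plexus and meningeal markers had the largest mean differences. Of 10 choroid plexus markers 9 were lower, with a mean log2 fold change of -2.07 (adjusted p = 0.00134, and adjusted p = 0.719 with an estimated correlation), and 6 passed adjusted over the list alone. Ttr, the transthyretin gene that the choroid plexus epithelium expresses at a high level, was at 3556 CPM in untreated replicate 2 and 627 CPM in untreated replicate 5, against 2.81 to 61.5 CPM in the other 8 libraries. Kl, Clic6 and Folr1 had log2 fold changes of -3.89 ± 1.09, -2.98 ± 0.921 and -2.93 ± 1.05 (SE). Of 15 meningeal fibroblast markers 12 were lower, with a mean of -0.62 (adjusted p = 4.29e-05, and adjusted p = 0.662 with an estimated correlation), and 5 passed adjusted over the list alone. Lum was at 10.2 ± 4.47 and 4.50 ± 0.61 CPM (SD, n = 5 each). Igfbp2 and Igf2 reached 109 and 285 CPM in untreated replicate 2. Without untreated replicates 2 and 5, an alternative chosen after the data were seen, 536 genes had an unadjusted p under 0.05 in place of 1070, and edgeR called 0. The choroid plexus mean then was -0.06 and no longer passed (adjusted p = 0.677), and the meningeal mean was -0.25 (adjusted p = 0.00214, and adjusted p = 0.771 with an estimated correlation; up to 0.306 over the alternatives). Over the 31 alternatives the choroid plexus call was kept in 27 and the meningeal call in 30.

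**Figure D2:**
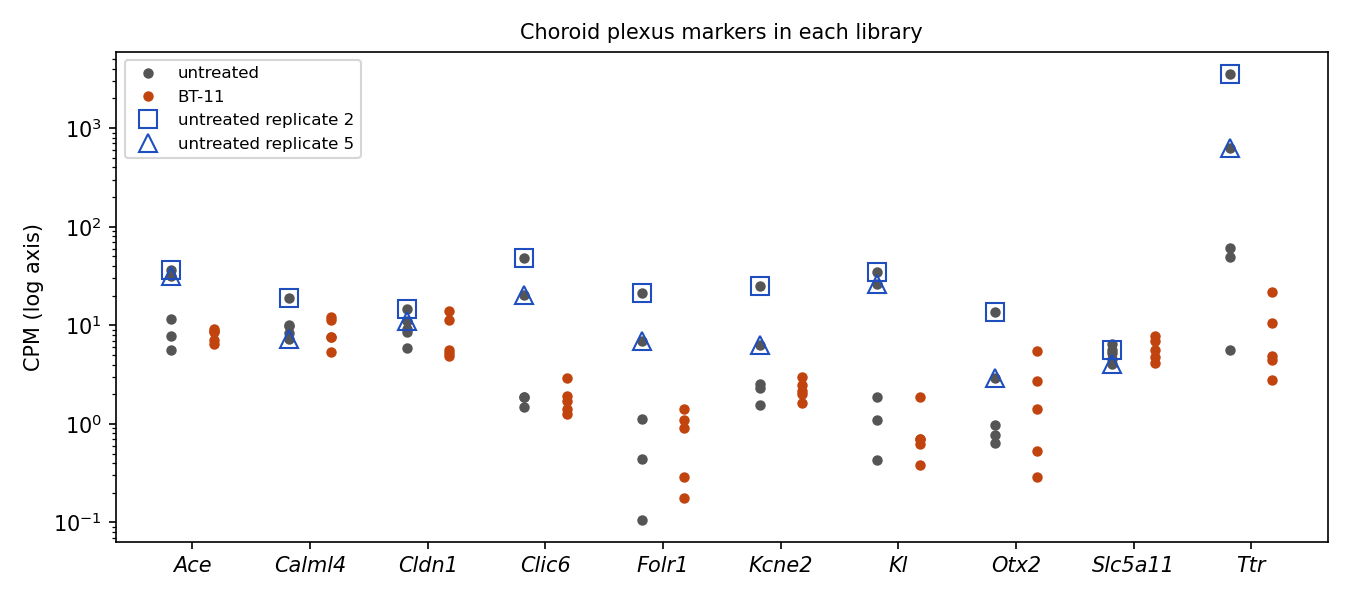
CPM on a log axis of the 10 tested choroid plexus markers in each untreated (grey) and BT-11 (orange) library, with untreated replicate 2 marked by squares and untreated replicate 5 by triangles. These 2 libraries hold the highest values for 6 of the 10 genes, including Ttr at 3556 and 627 CPM.

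**Figure D3:**
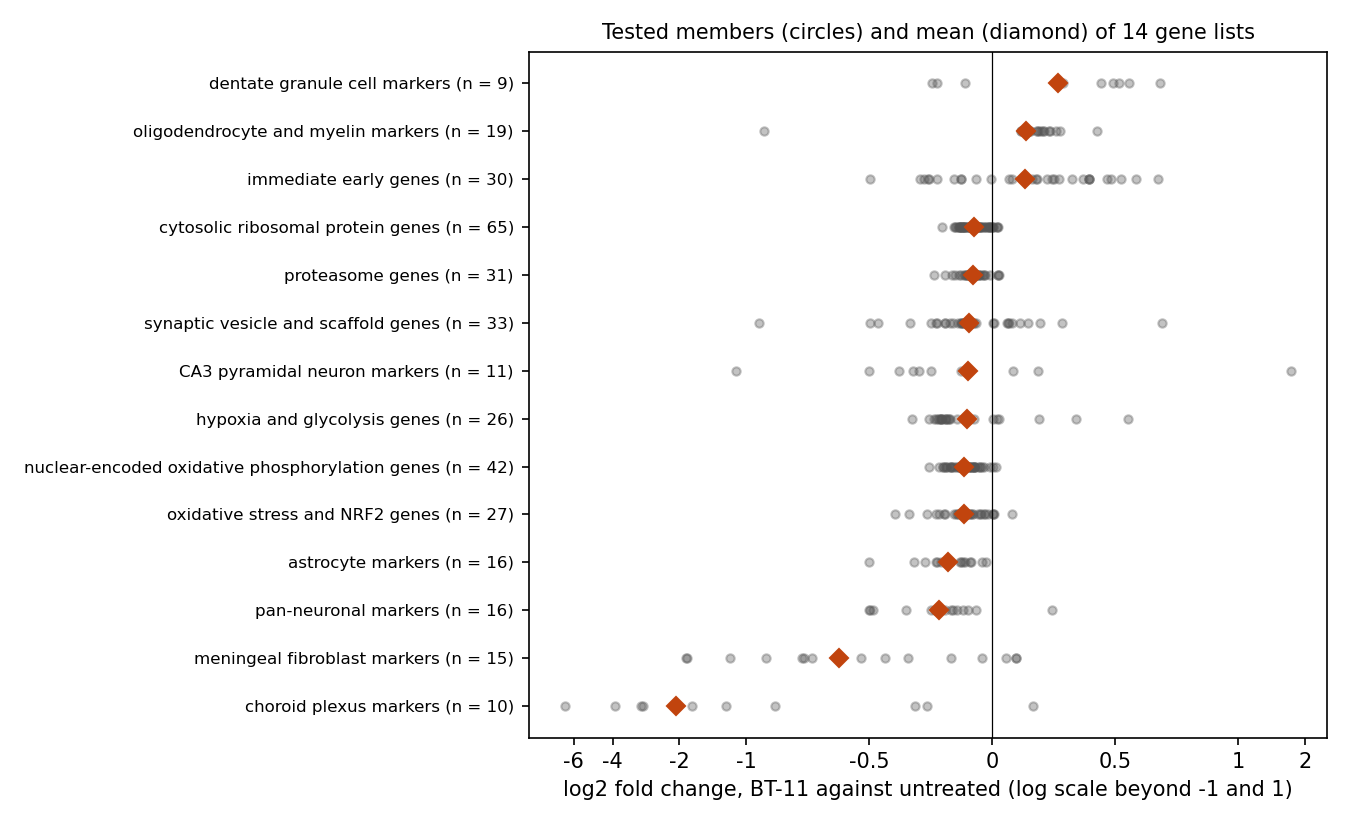
Log2 fold change (BT-11 against untreated, log scale beyond -1 and 1) of each tested member (grey circles) and the mean (orange diamond) of the 14 gene lists past an adjusted p of 0.05 with a preset correlation; n is the number of tested members. Means run from 0.27 for dentate granule cell markers to -2.07 for choroid plexus markers, and no list passed with an estimated correlation.

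Inflammatory, immune and lipid gene groups did not pass in either direction in this test. Of 14 homeostatic microglia markers 10 were higher (adjusted p = 0.465), and of 20 plaque-associated microglia genes 14 were lower (adjusted p = 0.0605). All 7 MHC class II genes were lower, by a mean of -0.22 (adjusted p = 0.0706). The adjusted p was 0.103 for 27 interferon response genes, 0.275 for 18 complement genes, 0.724 for 16 MHC class I genes and 0.981 for both 15 NF-kappaB and cytokine genes and 17 reactive astrocyte genes. It was 0.449 for 11 LANCL and anti-inflammatory cytokine genes, 0.112 for 22 PPAR and lipid handling genes and 0.0533 for 23 cholesterol synthesis genes. Some of these calls depend on the fit: without untreated replicates 2 and 5, plaque-associated microglia and MHC class II genes (adjusted p = 0.00815 for both) and cholesterol synthesis genes (adjusted p = 0.0158) passed as lower, each with an adjusted p of 0.771 with an estimated correlation. Over the 31 alternatives, the 3 lists passed in 12, 9 and 13. With the replicate block they passed as lower too (adjusted p = 0.017, 0.0104 and 0.0382 in camera). With the block and an estimated correlation none did (adjusted p = 0.586, 0.586 and 0.598). Blood cell markers, 5 higher and 2 lower, had a mean of 0.90 and did not pass (adjusted p = 0.223). They passed as higher in 4 of the 31 alternatives. With the replicate block they passed too (adjusted p = 0.000973, and adjusted p = 0.498 with an estimated correlation). Their score difference of 0.69 was 0.37 without BT-11 replicate 2. In all, 14 of 46 tested lists passed with the preset correlation, 11 lower and 3 higher, and 0 passed with an estimated correlation, with a smallest adjusted p of 0.662. Of the 14, 8 had the same direction in numbers 1 to 3 and in numbers 4 and 5, and 2 passed in both, pan-neuronal and choroid plexus markers, but with an estimated correlation 0 lists passed in either set. The choroid plexus call in both sets is not independent support, since each set holds 1 of the 2 untreated libraries high in these markers. Without untreated replicates 2 and 5 the choroid plexus mean was -0.06 and the list did not pass camera's test (adjusted p = 0.677). The self-contained test fry, which asks whether a list's genes move on balance in 1 direction, also passed 0 lists, with a smallest adjusted p of 0.233.

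Per animal, marker scores for 18 cell types and neighbouring regions differed by less than the test could separate. The pan-neuronal score was 0.10 ± 0.114 in untreated and -0.10 ± 0.133 in BT-11 rats (SD, n = 5 each; exact permutation p = 0.0317, adjusted p = 0.476, two-sided). BT-11 replicate 2 stood apart at -0.34, and without it the difference was -0.15 in place of -0.20. That library also had the highest thalamic (0.792), striatal (0.772) and blood cell (1.595) scores of all libraries. Its CA1 score was the lowest (-0.794), while its neocortical score was not high (-0.133). Whether tissue of neighbouring regions contributed to its low pan-neuronal score was not tested and stays open. The choroid plexus score was 0.60 ± 1.55 and -0.60 ± 0.271 (exact permutation p = 0.127, adjusted p = 0.476), a difference of -1.21 that ran from -1.57 to -0.65 with each library left out in turn, the latter without untreated replicate 2. The oligodendrocyte score was -0.07 ± 0.234 and 0.07 ± 0.349, and the homeostatic microglia score -0.02 ± 0.128 and 0.02 ± 0.0704, with exact permutation p of 0.468 and 0.595. The oligodendrocyte difference of 0.14 was 0.06 without untreated replicate 4 and 0.29 without BT-11 replicate 3. The homeostatic microglia difference of 0.047 was -0.005 without untreated replicate 2. The smallest p that 252 assignments of the labels can give is 0.00794, or 0.143 adjusted over 18 scores, so that no single score could pass, and 0 of the 18 did. Ribosomal RNA genes took 4.71 ± 0.612% of the counts in untreated and 5.48 ± 1.22% in BT-11 libraries (exact permutation p = 0.278), and Rn18s alone 1.77 ± 0.254% and 2.704 ± 0.838% (exact permutation p = 0.0317, adjusted p = 0.143 over 9 library measures).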

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

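In this part, both tests on the choroid plexus markers were chosen only after their result was seen, and the omission of pairs of untreated libraries was chosen after the data were seen. Within a group of 5 libraries, a value was picked out when its gap to the nearest other library, divided by the range of the group, exceeded Dixon's critical value of 0.71. This held for 18 of 222 groups of values (8.11%), where chance picks about 1 in 20.

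Untreated replicate 2 stood apart for 4 measures. Its Ttr level was 3556 CPM against 5.67 to 627 in the other untreated libraries (ratio 0.825), Igfbp2 109 against 13.7 to 32.6 CPM (0.803) and Igf2 285 against 23.8 to 85.1 CPM (0.765), while its homeostatic microglia score was -0.25 against 0.01 to 0.06 (0.826). Untreated replicate 3 held more Wfs1, at 284 against 91.9 to 130.3 CPM (0.8), and more Dclk3, at 12.1 against 8.26 to 9.05 CPM (0.793). Untreated replicate 1 held more Aif1, at 34.3 against 21.1 to 24.8 CPM (0.717), and untreated replicate 5 had the largest total count of its group (0.842).

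Among the BT-11 libraries, replicate 2 was low in the pan-neuronal score, at -0.34 against -0.07 to -0.01 (0.802), in Lancl2, at 50.2 against 58.4 to 61.3 CPM (0.733), in Pkm, at 847 against 966 to 1006 CPM (0.75), and in Stx1a, at 65.6 against 98.7 to 111 CPM (0.723). Without passing this rule, replicate 2 also had the highest thalamic (0.792) and striatal (0.772) and the lowest CA1 score (-0.794) of all libraries. A share of tissue from neighbouring regions therefore stays open for its low values. Replicate 1 was high in the neocortical score (0.769), in Kl at 1.87 CPM (0.788) and in Psmc2 at 146 CPM (0.723). Replicate 1 was low in Cttnbp2 at 196 CPM (0.742). The dentate granule cell score of replicate 4 was low, at -0.21 against 0.19 to 0.30 (0.786), and Opalin in replicate 3 was low, at 110 against 203 to 224 CPM (0.812).

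The choroid plexus markers lower with BT-11 no longer passed as a list without untreated replicates 2 and 5. The score difference then was -0.13, with an SD of 0.271 among BT-11 scores, but as they are the 2 highest untreated libraries in this score, leaving them out lowers the difference in any case, and a treatment difference stays open. Choroid plexus tissue carried over at dissection is a candidate source that stays open: 6 of the 10 tested markers, among them Ttr at 3556 and 627 CPM, had their highest values in these 2 libraries, while Slc5a11 was at 4.07 to 7.82 CPM in all 10. Without the pair, the genes at an unadjusted p under 0.05 went from 1070 to 536, where 20 simulations of these 3 against 5 libraries with no change gave 501 to 617 (mean 564). These simulations drew each gene on its own, without variation that genes share. Other splits of the 10 real libraries gave 95 to 2794 such genes, so a count within the simulated range does not decide the source. Carried-over tissue would give the drop to 536, but the drop is not specific to the pair, since leaving out untreated replicates 2 and 4 gave 513, and the 10 pairs of untreated libraries ran up to 2206.

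Chance cannot be excluded for the counts of single genes. As many as 1070 genes at an unadjusted p under 0.05 came from 16 of 100 splits of the 10 libraries, the real one included, and the highest other split gave 2794. As many as the 40 genes called by DESeq2 came from 6 of 40 splits, and the highest other gave 917. Splits that call several times the real count point to a structure of the samples other than the treatment. The splits with 2794 and 2532 genes put all libraries numbered 4 and 5 on the same side. The treatment divides these libraries evenly. Other even splits, with 1478 and 1152 genes, reached 1070 as well, so even splits do not exclude chance either. The share of 16 in 100 thus partly counts the difference between these numbers and the rest, and does not settle chance. In DESeq2, the splits above 40 were uneven with 917 and 625 genes and even with 178, 97 and 51.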

How the results depend on the processing

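EdgeR's count of 0 genes at an adjusted p of 0.05 moved under DESeq2 (40 genes, 13 higher and 27 lower) and without untreated replicate 3 (62 genes, 31 higher and 31 lower); leaving out each library in turn gave 0 to 62 genes, with 751 to 1476 at an unadjusted p under 0.05, and 9 to 19 lists, the lowest without untreated replicate 1. The genes at an unadjusted p under 0.05 moved to 367 with the choroid plexus score as a covariate and, in alternatives chosen after the data were seen, to 536 without untreated replicates 2 and 5 and to 327 with choroid plexus, thalamic and CA1 scores. With an estimated correlation 0 lists passed in place of 14. Among lists past the test in either fit, means reversed for ribosomal protein genes with 1 surrogate variable (0.047), without untreated replicate 1 (0.0205, the range without each library being -0.143 to 0.0205), without untreated replicates 1 and 2 (0.0948) and with the 3 scores (0.0778), past the test as higher in the first and the last 2 of these fits (adjusted p = 0.0234, 3.35e-06 and 0.00615); for choroid plexus (0.0434) and ependymal markers (0.45) with the choroid plexus score; for myelin markers with the oligodendrocyte score (-0.0225); without untreated replicates 1 and 2 for oxidative phosphorylation (0.011), proteasome (0.0158) and glucocorticoid-responsive genes (0.145); and with the 3 scores for oxidative phosphorylation (0.00797) and proteasome genes (0.0248). With an estimated correlation the 3 calls of ribosomal protein genes as higher did not pass camera's test (adjusted p = 0.893, 0.748 and 0.895, in the same order). Lists past in neither fit changed sign too, 129 times over 1517 list means, from 0 to 15 per alternative, the most with the 3 scores (15) and without untreated replicates 1 and 2 (11). The cause was not tested, except that a score in the design removes its own list's difference by construction. Same-numbered libraries were not treated as pairs, since the correlation of their deviations was 0.221, 0.157, 0.155, 0.169 and 0.0418, with 4 of 5 over 0.1 and 1 of 5 closest to its own number; this leaves open the structure that numbers 4 and 5 share across groups. The replicate block gave 0 genes, 0 higher and 0 lower, 1320 genes at an unadjusted p under 0.05 and 20 lists, 14 of them shared. The other 6 were plaque-associated microglia (adjusted p = 0.017), MHC class II (0.0104) and cholesterol synthesis genes (0.0382), lower, and CA1 markers (8.54e-05), blood cell markers (0.000973) and glutamate receptor genes (0.028), higher; with an estimated correlation 0 passed (smallest adjusted p = 0.498). The 18 marker scores are too many for a single one to pass (0.143 at best), so their stability was not tested by a call. Depth limited genes such as Tnf, at 0 to 4 counts per library.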

Other observations

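In this part, the split by replicate number was picked after its counts had been seen, and so were the tests of chance, transcript length and ribosomal RNA made on it; the tests of the gene lists were planned except the omission of untreated replicates 1 and 2 and the removal of the length trend.

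Libraries numbered 4 and 5 differed from those numbered 1 to 3 in both treatment groups. With the treatment in the design, edgeR called 531 of 11870 genes, 333 higher and 198 lower in numbers 4 and 5. Prkca, which encodes a protein kinase C, was higher by 0.74 ± 0.0691 (log2, SE), at 171 to 180 CPM in the 4 libraries and 94.3 to 116 CPM in the 6 others. Lifr, a cytokine receptor gene, was higher by 0.96 ± 0.117 and Synj1, a synaptic phosphatase gene, by 0.49 ± 0.0648. Genes that glucocorticoids induce were lower: Sgk1 had -1.02 ± 0.156, Ddit4 -0.81 ± 0.0919 and Nfkbia -0.90 ± 0.122, while Fkbp5, also induced by glucocorticoids, had 0.03 ± 0.127.

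Of 22 glucocorticoid-responsive genes 5 were called, all lower in numbers 4 and 5 (list adjusted p = 1.54e-08, and adjusted p = 0.582 with an estimated correlation). Of 30 immediate early genes 9 were called, all lower, among them Nr4a1 at -0.87 ± 0.142 (adjusted p = 2.93e-07, and adjusted p = 0.582 with an estimated correlation). Of 65 cytosolic ribosomal protein genes 33 were called, all lower, and the list mean was -0.31 (adjusted p = 1.46e-38, and adjusted p = 0.582 with an estimated correlation). Of 24 glutamate receptor genes 3 were called, all higher. The differences followed transcript length (Spearman correlation 0.43 across genes): with genes in 4 equal groups by length, 145 of 175 called genes in the shortest group were lower and 176 of 185 in the longest were higher. With each library's length trend removed, the list mean went from -0.31 to -0.14 for ribosomal protein genes and from 0.25 to 0.15 for glutamate receptor genes, but from -0.36 to -0.38 for immediate early and from -0.346 to -0.354 for glucocorticoid-responsive genes. The interaction of this split with the treatment called 0 genes, with a smallest adjusted p of 0.227.

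No batch is given in the labels, and no biological explanation of this split was tested. Among 100 splits of the 10 libraries into 4 and 6, only the real one called as many as 531 genes and the highest other called 5; since numbers 4 and 5 were picked as the largest of 10 pairs of numbers, this overstates how far chance is excluded, and the pair 1 and 2 called 158. A choroid plexus share as its cause is argued against by the libraries high in that score, which lie on opposite sides of the split. These were untreated replicate 2 (2.82) and untreated replicate 5 (1.61). With the score in the design 380 of the 531 genes kept their call. That fit cannot decide the question, since a score high on both sides could remove little of the split. With each library's trend with transcript length removed, 87 of the 531 kept their call and the median size of the change went from 0.39 ± 0.085 to 0.31 ± 0.0785 (log2, median SE), with 530 signs kept. Most calls thus ended while most of the size stayed in these genes. As they were picked by the fit that keeps the trend, the size that stayed may be overstated. How much of the split the length trend accounts for therefore stays open. All 4 libraries had a lower share of ribosomal RNA than the 6 others (4.31 ± 0.447% against 5.62 ± 0.917%, exact permutation p = 0.0238). A difference in RNA preparation or integrity between these sets is therefore a candidate explanation, and handling of the animals, which the lower glucocorticoid-induced genes could reflect, was not tested.

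Within numbers 4 and 5, the 479 genes called between BT-11 and untreated rats exceeded those of every other pair of numbers taken alone (0 to 102 genes), and the other 2 splits of these 4 libraries called 0. With 3 splits in all, no share under 0.05 can be reached.

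The 14 lists past camera's test with a preset correlation were no more than other splits gave: 52 of 100 splits passed as many, the highest passed 24, and the median over the other splits was 14. Members that vary together between animals, counted as nearly independent, may therefore account for the number of lists. A trend with transcript length as the whole cause is argued against, since 13 of the 14 lists, all but ribosomal protein genes, kept their call with it removed. A dependence on untreated replicates 1 and 2 alone is argued against for the 8 of 14 that kept their call without them and stays open for the other 6. Whether any of the 14 differences comes from BT-11 stays open.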
